A study of Arabidopsis thaliana with 4 samples.

How the data were processed

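Transcript levels were measured with Affymetrix ATH1 arrays in the aerial parts of Arabidopsis thaliana seedlings harvested 2 weeks after germination. Per the labels, 2 arrays came from the wild type Col-0 and 2 from aln-1, a mutant of the allantoinase gene ALN in the Col-0 background, and each array was a separate biological replicate. Arrays were grouped by genotype from their titles, and the only comparison was aln-1 against wild type.

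The deposited table held 22746 probe sets on 4 arrays as log2 values. Per the submitters' processing notes, signals were made with MAS5; its version, its scaling target and the step that produced the logarithms are not given in the sources used here. The middle pair of the 4 values of a probe set added up to 0 within 2e-06 in all 22746 rows, so each deposited value is a log ratio to that probe set's own median over the 4 arrays, and the signal level itself is not in the values. The base of the logarithm is not stated. It was taken as 2 from the rounding steps of the single precision values. With base 2, 59.3% of the probe sets had no readable step or a step that belongs to signals of at least 256. With natural logarithms the same step would belong to signals of at least 2981. Fold changes below rest on that base. Array medians of the deposited log2 values were 0.04 and 0.02 for the wild type arrays and -0.02 and -0.04 for the aln-1 arrays. Detection calls were not used here, the number of arrays limits the precision, and no probe set could be called absent. In 453 rows at least a pair of arrays held exactly equal values; 118 rows had equal lowest values on both aln-1 arrays and 104 on both wild type arrays. For a named gene of this kind the lower group is read as being at a lower limit, and its fold change is given as at least the printed value. That a limit was set is not stated in the sources used here; without one these values are plain fold changes.

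Values were analysed as deposited, with R 4.3.3 and limma 3.58.1. Each probe set was fitted with lmFit on genotype and tested with eBayes, two-sided, and p-values were adjusted with the Benjamini-Hochberg method over all 22746 probe sets, with an adjusted p threshold of 0.05. The design written before the data were examined had assumed signal levels: a filter on dim probe sets, a pseudocount and a variance trend over the signal. None of these can be formed from values centred per probe set, so the tests used no filter, no pseudocount and no trend. A count of probe sets 2-fold apart in all 4 pairs of an aln-1 array and a wild type array needed no model, and was repeated for the other 2 of the 3 splits of the arrays into pairs. With 2 arrays against 2, a two-sided permutation test of a single gene cannot go below p = 0.333, so no such test is printed, and 33.3% of probe sets separate the genotypes by chance when no size limit is set.

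A brightness class was read from the rounding steps, because a single precision number keeps a coarser step the larger it is. It placed 13484 probe sets in a bright, 6526 in a middle and 2736 in a dim class, with median within-genotype SDs of 0.16, 0.33 and 1.01 on the log2 scale. By these steps the dim class belongs to signals below 16 and the bright class to signals of at least 256. The class is approximate, since a dim value can carry a coarse step by chance. The step was read after centring on the row median, so a gene low in 1 genotype may be classed as dim although brighter in the other. Rows without a readable step, such as the 34 rows at 0 on all arrays, were counted as bright. It served in alternatives chosen after seeing the data.

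Gene names came from the array's annotation, updated through gene identifiers to a RefSeq gene table of the assembly TAIR10.1, which was used only for names and for which genes lie next to each other. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 were not listed and are unnamed here; 13436 of those with 1 gene matched the table. The 28 gene lists were fixed before the data were examined. Of their 504 members, 501 matched by locus and symbol, and 57 of these, 54 different genes, had a named probe set of their own. A list with at least 5 measured members was tested with camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists tested. This preset takes the genes of a list as nearly independent, so the p-value does not cover a spread between arrays that they share. Where a list is said to pass "adjusted over the list alone", the limma p-values of its measured members were adjusted among themselves. For lists with few members this adjusts little or nothing. Passing there is weak evidence, as 5332 of the 22746 probe sets had an unadjusted limma p under 0.05.

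The rule for named genes was also fixed before the data were examined. It takes ALN and the measured purine catabolism genes, then the 8 higher and 8 lower probe sets with the largest log2 fold change among those past the threshold that had 1 gene and no overlap between genotypes. It adds up to 4 members with the smallest p from each other list on abscisic acid or jasmonate, and up to 2 from each remaining list. Members that did not pass are given as values only.

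The tests were run on simulated data with the layout of this comparison, with log2 changes put into 200 of 22746 probe sets. Normal noise was drawn with each probe set's own SD within genotypes. These SDs come from 4 arrays and are scattered themselves, so the simulated spreads scatter more than the measured ones. The measured data had 5332 probe sets at an unadjusted limma p under 0.05, far more than the 200 changed here. The rates below therefore need not hold for the measured data. The limma test called 0 of 50 probe sets changed by 1 on the log2 scale, 1 of 50 changed by 2, 18 of 50 changed by 4 and 29 of 50 changed by 6, and 1 unchanged probe set. The rule of 2-fold separation found 147 of the 200 changed probe sets and 402 unchanged ones. With lists of 5 genes shifted by 1.5, camera found 200 of 200, against 3 of 200 unshifted lists. These counts used an unadjusted p under 0.05 and independently drawn genes of the bright class. They do not cover lists whose genes move together.

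Alternatives were centring each array on its median, the replicate number as a block, leaving out each array in turn, and thresholds of 0.1 and 0.01. For lists they were an estimated correlation, fry, and the mean of all probe sets per gene. Alternatives chosen after seeing the data were variance priors fitted within brightness classes, a robust prior, and leaving out the dim class or the probe sets with equal values.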

Results

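The arrays measured transcript levels in the aerial parts of 2-week-old seedlings of wild type Col-0 and of aln-1, with 2 biological replicates of each genotype. ALN encodes allantoinase, the enzyme that hydrolyses allantoin in purine breakdown, and its mutant accumulates allantoin. The comparison asked which transcripts differ in the mutant, with abscisic acid (ABA) metabolism and abiotic stress in view. Values are log2 signals relative to each probe set's median over the 4 arrays, given as mean ± SD with n = 2 arrays per genotype, and differences are aln-1 minus wild type with their standard error (SE).

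The ALN signal was 1.81 ± 0.31 in wild type and -1.66 ± 0.09 in aln-1 (SD, n = 2 each), a difference of -3.46 (SE 0.22) or 11.03-fold. Both aln-1 arrays, at -1.59 and -1.72, lay below both wild type arrays, at 1.59 and 2.03. In the limma test over all probe sets ALN had an adjusted p of 0.0580 and did not pass the threshold of 0.05; adjusted over the list alone its limma adjusted p was 8.72e-04, and 1 of the 3 measured purine catabolism genes passed. The other measured genes of the pathway act after allantoinase. Allantoate amidohydrolase, AAH, differed by 0.38 (SE 0.20) and ureidoglycolate amidohydrolase, UGLYAH, by 0.38 (SE 0.48), and neither passed; with each array left out in turn they ranged from 0.23 to 0.53 and from -0.22 to 0.98. Where the aln-1 insertion lies relative to the ALN probes is not given in the sources used here, so the signal checks the array labels only as far as the transcript under the probes is affected. With a variance prior fitted within brightness classes, chosen after seeing the data, the limma adjusted p of ALN was 0.0217.

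Among the named genes that passed the limma threshold over all probe sets, AT1G66660 rose by 7.19 on the log2 scale (SE 0.33) and AT5G47980, a BAHD acyltransferase gene of the thalianol gene cluster, by 6.83 (SE 0.18). AT4G16900, a disease resistance gene of the TIR-NBS-LRR type, rose by 5.98 (SE 0.20). BSMT1, a methyltransferase that makes methyl salicylate and methyl benzoate, rose by 5.35 (SE 0.22), from -2.65 ± 0.19 to 2.70 ± 0.26 (SD, n = 2 each). The neighbouring genes AT4G01920 and AT4G01910 rose by 5.70 and 5.14, AT5G43030 rose by 5.47, and the pseudogene AT4G04410, whose wild type arrays held equal lowest values, was at least 48.4-fold higher. Among the named genes that fell and passed, the transcribed pseudogene RSU1 was at least 149.9-fold lower, with equal lowest values on both aln-1 arrays. Both of these bounds read the equal values as a lower limit of the signal, which the sources used here do not state. The pseudogene AT5G34920, whose probe set is of a type marked as shared between similar transcripts, fell by 6.50 on the log2 scale, and AT5G24240, a phosphatidylinositol 4-kinase gene, fell by 5.93 (SE 0.23). AT1G63540, AT1G60970, AT1G70870, AT3G22940 and AT5G15360 also fell, with differences of -5.84, -5.76, -5.29, -5.04 and -4.96. The limma adjusted p of these 16 genes lay between 0.0459 and 0.0491. Of them, AT4G16900, AT4G04410 and RSU1 were in the dim class, whose rounding step belongs to signals below 16. The median within-genotype SD was 1.01 in that class against 0.16 in the bright class. Signal over background is not in the values, so the bounds for AT4G04410 and RSU1 may rest on signals near background and are not firm. Among the called probe sets that are unnamed here were 248729_at and 248727_at with differences of 11.42 and 10.48, and 249082_at with -8.35.

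In all, limma called 58 of 22746 probe sets at an adjusted p under 0.05, of which 35 were higher and 23 lower in aln-1, and all 58 differed by at least 2-fold. Of these, 39 had 1 named gene, 21 of them higher and 18 lower. At an unadjusted p under 0.05 there were 5332 probe sets. Without wild type replicate 1, wild type replicate 2, aln-1 replicate 1 or aln-1 replicate 2, limma called 0 probe sets, with a smallest adjusted p of 0.289, 0.225, 0.176 and 0.255 and with 2953 to 5326 at an unadjusted p under 0.05, while the log2 differences of the 16 genes above moved by at most 0.39. The count also depended on the variance prior chosen, with 675 calls from priors fitted within brightness classes and 0 from a robust prior (5084 at an unadjusted p under 0.05), both chosen after seeing the data.

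Without a model, 1868 probe sets were at least 2-fold apart in all 4 array pairs, 1062 higher and 806 lower in aln-1. The other 2 splits of the 4 arrays, each of which puts 1 array of each genotype on both sides, gave 434 and 411 probe sets. In these splits limma called 0 probe sets, with 603 and 597 at an unadjusted p under 0.05. A genotype difference adds to the spread within each side of these splits. Their counts can therefore lie below what chance alone would give, and they are no measure of chance in the genotype split. Leaving out 1 array loosens the rule to 2 pairs, and the count was then 2932 without wild type replicate 1, 3497 without wild type replicate 2, 3966 without aln-1 replicate 1 and 3066 without aln-1 replicate 2.

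**Figure D1:**
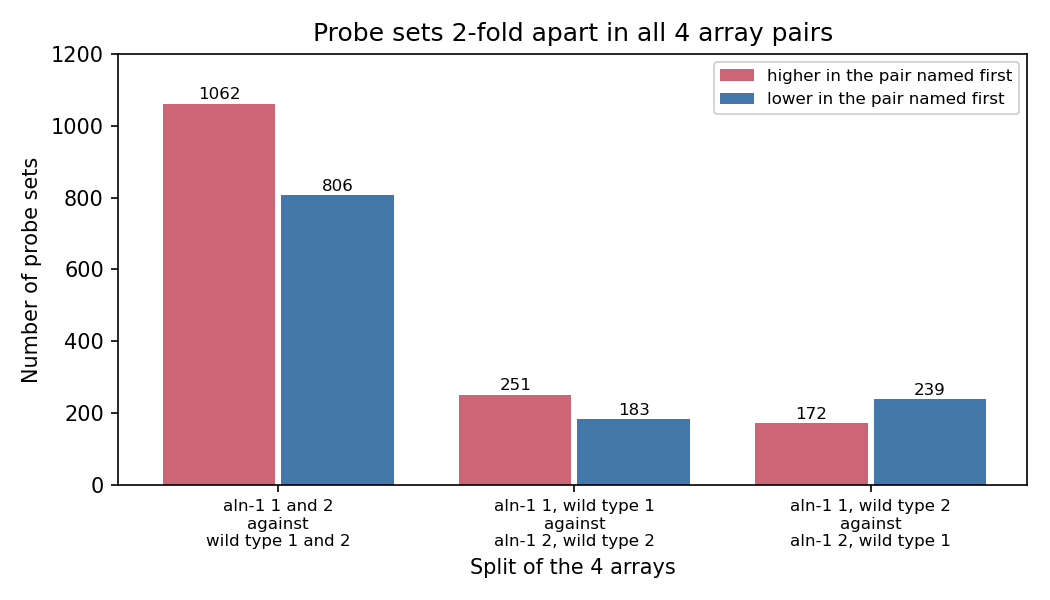
Number of probe sets at least 2-fold apart in all 4 array pairs, on a linear axis from 0, for the genotype split and the other 2 splits of the 4 arrays; bars show probe sets higher and lower in the pair of arrays named first. The genotype split gave 1062 and 806 probe sets, and no other bar is above 251. A probe set counted as 2-fold apart by genotype cannot also be counted in another split, so those bars are no measure of chance alone.

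The measured genes of the ABA and drought response list were higher in aln-1 in all 5 cases. The list held 45 genes, of which 5 had a named probe set, and all encode proteins of the late embryogenesis abundant or cold-regulated kind that accumulate in drying or chilled tissue. LEA4-5 differed by 2.99 (SE 0.36), from -1.31 ± 0.10 in wild type to 1.68 ± 0.61 in aln-1 (SD, n = 2 each). COR15A differed by 1.70 (SE 0.14), COR15B by 1.50 (SE 0.14), COR47 by 1.44 (SE 0.19) and LTI30 by 1.91 (SE 0.37), the last named outside the rule because it completes the list. For each of the 5, both aln-1 arrays lay above both wild type arrays. As a set they rose against the other probe sets (camera in limma, adjusted p = 1.45e-05), with a median difference of 1.70; with an estimated correlation the adjusted p = 0.131. None of the 5 passed in the limma test over all probe sets, with adjusted p from 0.0698 to 0.129, and 5 of 5 passed adjusted over the list alone. COR15A, COR15B and COR47 were also the 3 measured members of the 13-gene cold regulon list, and 3 of 3 passed adjusted over the list alone. In the same arrays the root markers EXPA7 and EXPA18 differed by 1.43 and 1.14, in the same direction, and PYK10, the other measured root marker, by 0.20. STZ, a zinc finger gene placed on the rapid handling and touch list, differed by 1.47, also in the same direction. Whether STZ rose through handling or through a stress response was not tested.

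The few measured genes of ABA synthesis and breakdown showed small differences. No NCED or CYP707A gene of the list had a named probe set of its own, so those steps were not covered. Of 18 genes 3 were measured, and 0 of 3 passed over all probe sets or adjusted over the list alone. UGT71B6 and UGT71C5, which glucosylate ABA, differed by -0.77 (SE 0.20) and 0.05 (SE 0.18), and the beta-glucosidase gene BGLU33 by -0.50 (SE 0.21). Without aln-1 replicate 2, UGT71C5 was at -0.11 and BGLU33 at -0.29. None of the 12 genes on the list of ABA receptors and kinases had a named probe set of its own, and that list was not analysed here.

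Jasmonate genes went in different directions. JMT, which makes methyl jasmonate, differed by 2.93 (SE 0.41) and OPCL1, which activates a jasmonate precursor, by 0.68 (SE 0.14), with both aln-1 arrays above both wild type arrays; these 2 were the measured members of the 19 genes of jasmonate synthesis and breakdown. The plant defensin genes PDF1.2 and PDF1.2b, which respond to jasmonate together with ethylene, differed by -3.74 (SE 0.54) and -5.70 (SE 1.29). The PDF1.2b probe set is of a type marked as able to bind transcripts of related genes, so these values need not be independent. The aln-1 arrays of PDF1.2b were far apart, with a mean of -3.43 ± 2.27 against 2.27 ± 0.63 in wild type (SD, n = 2 each). The transcription factor genes MYC3 and MYC4 differed by 0.13 (SE 0.14) and -0.05 (SE 0.18), the latter with a change of sign when arrays were centred on their medians; without aln-1 replicate 2 MYC3 was at 0.080, and without aln-1 replicate 1 MYC4 was at 0.077. In the limma test over all probe sets 0 of these 6 genes passed. Adjusted over the list alone, 2 of 2 synthesis and breakdown genes passed, both higher, and 2 of 4 measured members of the 32 response genes, PDF1.2 and PDF1.2b, both lower.

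**Figure D2:**
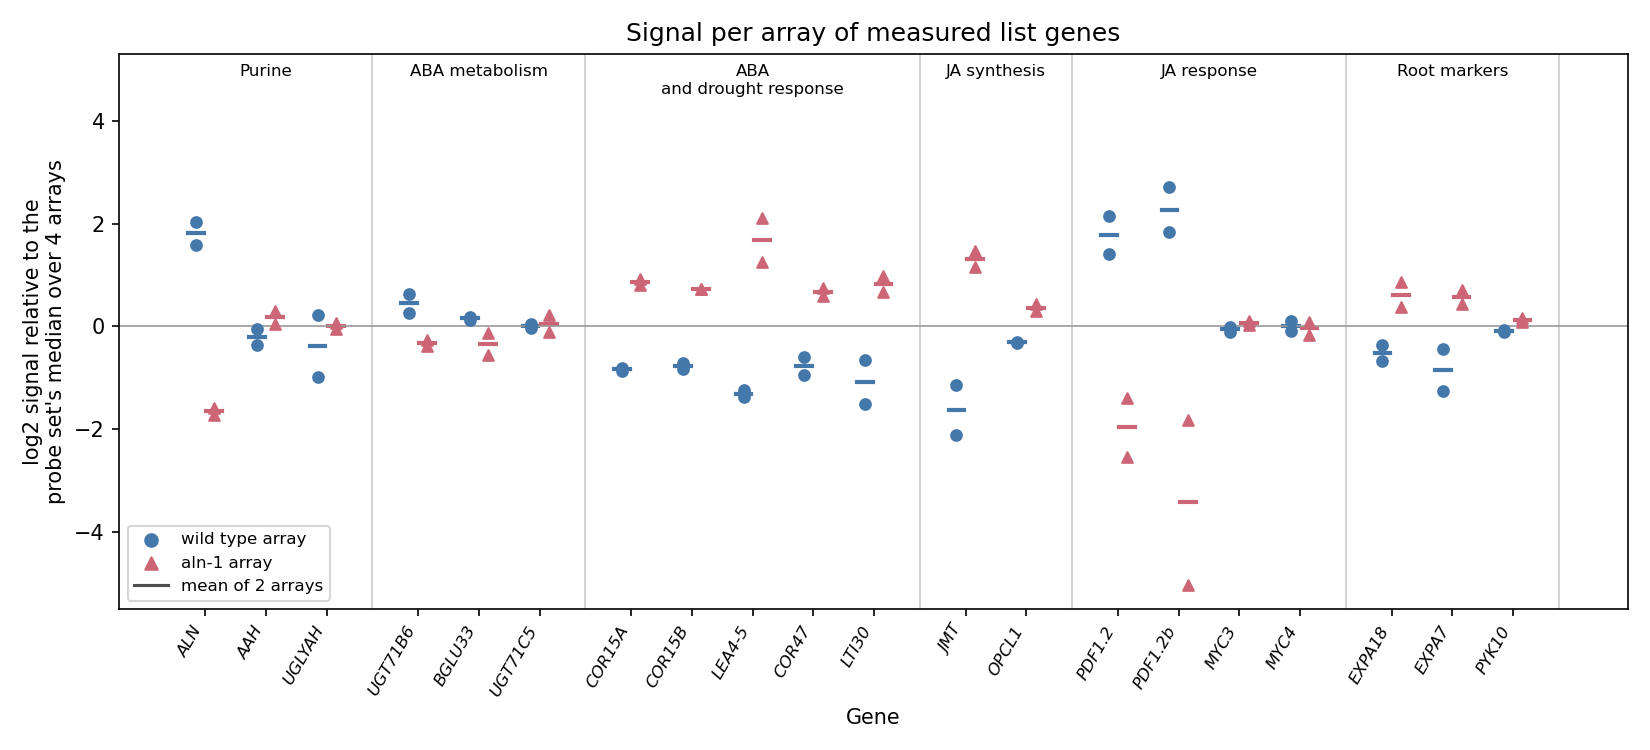
Log2 signal relative to the probe set's median over the 4 arrays (vertical axis) for each measured gene of 6 lists (horizontal axis); circles are wild type arrays, triangles aln-1 arrays and short lines the mean of 2 arrays. The aln-1 arrays lie above the wild type arrays for all 5 ABA and drought response genes and below them for ALN, PDF1.2 and PDF1.2b.

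Photosynthesis genes were slightly lower in aln-1. All 6 measured of 32 genes had a difference below 0, with a median of -0.32. On these arrays the root markers EXPA7, EXPA18 and PYK10 differed by 1.43, 1.14 and 0.20. The Calvin cycle genes SBPASE and PRK differed by -0.92 (SE 0.22) and -0.88 (SE 0.24). As a set the 6 genes fell against the other probe sets (camera in limma, adjusted p = 0.0383). With an estimated correlation the camera adjusted p was 0.421. For LHCB4.1 and PSAE-1 an aln-1 array lay above a wild type array. The preset correlation does not cover a spread between arrays that these genes share, so chance stays open. Of the 6 genes 0 passed over all probe sets or adjusted over the list alone. The camera adjusted p was 0.138 without wild type replicate 1 and 0.0726 without aln-1 replicate 2.

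The remaining lists had 0 to 4 measured members each, too few for a set test, and 0 of their members passed in the limma test over all probe sets. WRKY53, a regulator of leaf senescence, differed by -1.99 (SE 0.35) and WRKY6 by 0.53 (SE 0.20); 1 of 3 measured senescence genes, WRKY53, passed adjusted over the list alone. SAG101, which acts in immune signalling, differed by -1.11 (SE 0.22) and GRX480 by -0.35 (SE 0.31); 1 of 2 measured salicylate and immune genes, SAG101, passed adjusted over the list alone. The heat shock gene AT5G48570 differed by 0.99 (SE 0.25) and was the 1 of 2 that passed in its list alone; the other, ATHSP22.0, differed by -0.23 (SE 1.71). The auxin conjugation gene WES1 differed by -1.01 (SE 0.33) and IAA29 by -1.11 (SE 0.50), and 0 of 4 auxin response genes passed in their list alone. The iron deficiency regulators BHLH101 and PYE differed by 1.12 (SE 0.42) and 0.07 (SE 0.15), and BCAT4 and UGT74B1 of glucosinolate synthesis by -0.87 (SE 0.26) and 0.12 (SE 0.15). DFR and UF3GT of anthocyanin synthesis differed by -0.54 (SE 0.24) and 0.36 (SE 0.22). The antioxidant genes GR and TAPX differed by -0.25 (SE 0.15) and -0.23 (SE 0.17). EIN3 of ethylene signalling differed by 0.09 (SE 0.14), the urease gene URE by -0.06 (SE 0.19) and the cell division kinase gene AUR1 by -0.08 (SE 0.16). In the lists of iron, glucosinolate, anthocyanin, antioxidant, ethylene, nitrogen and cell cycle genes, 0 members passed adjusted over the list alone. None of the genes in this paragraph was called over all probe sets, and those that follow moved by over 1.5 times on the log2 scale with 1 array left out. Without aln-1 replicate 2, WES1 was at -0.64, IAA29 at -0.56, WRKY6 at 0.33, TAPX at -0.086, EIN3 at 0.025, URE at 0.13 and AUR1 at 0.029. Without aln-1 replicate 1, GRX480 was at -0.014, UF3GT at 0.12, PYE at -0.038 and ATHSP22.0 at 1.36. Without wild type replicate 1, DFR was at -0.29 and UGT74B1 at 0.025, and without wild type replicate 2 BHLH101 was at 0.66.

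Markers of handling, time of day and other tissues were measured for few genes. The only measured gene of the rapid handling and touch list, STZ, differed by 1.47 (SE 0.27), and its unadjusted limma p of 0.00953 stands as the list's own value, 1 of 1 past the threshold. The evening clock gene GI differed by -0.07 (SE 0.13), and by -0.027 without wild type replicate 2. Of 20 root markers 3 were measured: the root hair expansin genes EXPA7 and EXPA18 differed by 1.43 (SE 0.36) and 1.14 (SE 0.25), and PYK10, an abundant beta-glucosidase of roots, by 0.20 (SE 0.13). Adjusted over the list alone 2 of these 3 passed, both higher. The guard cell gene FMA differed by -0.44 (SE 0.14). As the 1 measured member it passed in its list alone with its unadjusted limma p of 0.0470. The lists of morning clock genes, flower markers, seed storage markers, sulfur shortage and phosphate shortage had 0 measured members and were not analysed here.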

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

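Alternatives on variance priors, dim probe sets and equal values were chosen after seeing the data. The 58 limma calls fell to 0 with the replicate number as a block (4460 at an unadjusted p under 0.05), to 0 with a robust prior, to 0 at a threshold of 0.01 and to 0 without any 1 of the 4 arrays (0 to 0), and rose to 675 with priors fitted within brightness classes (649 of them 2-fold), 258 without the dim class and 1078 at a threshold of 0.1. Of the 58, 51 were shared with the 675 and 47 with the 258. Counts with a 2-fold limit were likewise 0 under the block, the robust prior and each array left out, and 258 without the dim class. Centring arrays on their medians gave 82, and leaving out equal values 66. Same-numbered arrays did not deviate together: over probe sets their deviations from the group means correlated at 0.0209 (genes are not independent replicates), and the block leaves fewer degrees of freedom. Leaving out an array also leaves fewer samples, with the lone array assumed to vary like the other genotype; the cause of the other changes was not tested. Probe sets 2-fold apart ranged from 2932 to 3966 with an array left out, where fewer pairs must differ. ALN kept its direction in all 10 alternatives (-3.68 to -3.24) and passed in limma with brightness priors (-3.46, adjusted p 0.0217) and without the dim class (adjusted p 0.0354). The median of the ABA and drought response list was 1.49 to 1.76 over 11 alternatives, with its camera call lost with the estimated correlation (median 1.70, adjusted p 0.131). The photosynthesis camera call was lost with the estimated correlation (median -0.32, adjusted p 0.421), without wild type replicate 1 (adjusted p 0.138) and without aln-1 replicate 2 (adjusted p 0.0726), with medians of -0.43 to -0.25 over the arrays left out. Fry, which tests for any shift of the list and not against other probe sets, gave an adjusted p of 0.0961 for it. Over 58 named genes and 575 pairs of a gene and an alternative, 461 kept direction and side of the threshold, 8 newly passed, 96 no longer passed and 10 turned. The 96 are the 16 called genes under 6 alternatives; their log2 differences moved by at most 0.39 with an array left out. Of the other 42 named genes, 21 moved by over 1.5 times (log2 scale) with an array left out. Those that turned were small or scattered: with each array left out in turn MYC4 ranged from -0.18 to 0.077 (0.0070 after median centring), UGLYAH from -0.22 to 0.98, UGT71C5 from -0.11 to 0.21, URE from -0.24 to 0.13, PYE from -0.038 to 0.18, AUR1 from -0.19 to 0.029 and ATHSP22.0 from -1.81 to 1.36. Quantile and cyclic loess normalization, the pseudocount, the dim filters and the variance trend were not run, because they need signal levels. The alternatives of no filter and no trend equal the fit reported, and the mean of all probe sets per gene changed nothing, as each tested list gene had 1 probe set. Signal over background is not in the values, so which calls it limits is not known.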

Other observations

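The genes in this first paragraph, and the tests of plastid genes, neighbouring genes, gene families and the region around ALN, were chosen after values of some of these genes had been seen; the permutation test of root genes and the count of shared probe sets were fixed before their results were seen, while the comparisons of array medians and the shuffle without 1 pair were added afterwards. With priors fitted within brightness classes, limma gave an adjusted p under 0.05 to 675 probe sets, and the genes below were picked from these by hand, so they stand as single values and not as a group. QQS, a gene that affects starch and protein content, differed by 8.08 (limma adjusted p 0.0469 with these priors), the glutathione transferase gene GSTU25 by 5.34, and the glycosyltransferase genes UGT78D1 and UGT76E12 by 4.88 and 4.24. The monoterpene synthase gene TPS-CIN differed by 4.10. The thionin genes THI2.1 and THI2.2 went in opposite directions, at 2.66 and -3.16. The drought-induced gene DI21 and the temperature-induced lipocalin gene TIL were higher, at 1.88 and 1.23. CSA1, a disease resistance gene, and the cytochrome P450 genes CYP71B23 and CYP71B36 were lower, at -2.60, -2.63 and -2.54. Of these genes, UGT78D1 alone passed in limma with 1 prior for all probe sets (adjusted p 0.0480). Over 44 families of genes that share a symbol, camera gave 0 with an adjusted p under 0.05 and 8 at an unadjusted p under 0.05. The lowest camera adjusted p was 0.148, shared by the 5 measured CRR genes at a median of -0.96 and the 8 measured rps genes at -0.48. These rps genes are plastid-encoded and are part of the 69 plastid genes below, so they are not a separate observation.

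Of 42 root hair and root peroxidase genes listed from textbook knowledge, 13 were measured and not yet seen, and 12 of the 13 were higher in aln-1, led by the peroxidase genes AT5G66390 and AT5G19890 at 1.50 and 1.30, although 0 of 13 passed alone in limma (adjusted p over all probe sets). Their median difference was 0.69, with a one-sided permutation p of 8.00e-04 over 10000 random sets of the same size and brightness. This p covers the choice of genes and not the spread between arrays, on which genes expressed together move together. The median of the 13 genes was -0.66 and -0.20 on the wild type arrays and 0.23 and 0.40 on the aln-1 arrays. The gap between the nearest arrays of the genotypes was 0.43, against 0.46 between the wild type arrays. The median difference of 0.69 was larger than both. With 2 arrays per genotype, a two-sided permutation test of the arrays cannot go below p = 0.333 whatever the effect, so it cannot decide. The rule fixed beforehand asked for a median above 0, most genes higher and a one-sided permutation p under 0.05. This rule was met, which counted for root tissue and against chance. It took no account of the spread between arrays, and the comparison of array medians was added after the result was seen. Root tissue left on the aln-1 seedlings and chance are therefore not told apart here. The labels give aerial parts, and PYK10 at 0.20 may have too high a level in wild type to show a small share. An effect of the genotype on such genes within aerial tissue stays open and was not tested.

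Plastid-encoded transcripts were mostly lower in aln-1, with 56 of 69 genes below 0. An equal log2 shift of all 69 genes, as from a common change in the share of plastid RNA, is argued against as the whole source by their spread. Their SD was 3.14 times their median SE. It was 2.35 times without rpoB, rpl33 and rps2, the 3 that passed in limma with priors fitted within brightness classes. No such ratio was computed for nuclear genes, and a change in plastid RNA that reaches the probe sets unevenly was not tested. The gene rpoB, for a subunit of the plastid RNA polymerase, was at -3.35 (limma adjusted p 0.0471), followed by rps18 at -1.52, rpl33 at -1.16, psaJ at -1.12 and petL at -1.11, with rps2 at -1.01. The median difference of -0.34 lay outside the middle 95% of 10000 random nuclear sets of the same brightness (-0.22 to 0.03). The median of the 69 genes was 0.25 and 0.07 on the wild type arrays and -0.08 and -0.18 on the aln-1 arrays. The gap between the nearest arrays of the genotypes was 0.15, against 0.18 between the wild type arrays. The median difference was larger in size than both. Chance stays open, as a two-sided permutation test of these arrays cannot go below p = 0.333. A genotype effect on some plastid transcripts stays open too, as does a common shift beside gene-specific ones.

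Among 415 genes with an unadjusted limma p under 0.01 and a difference of at least 2 on the log2 scale, 13 pairs within 20 locus numbers went the same way and 5 went opposite ways, including AT4G01910 with AT4G01920, at 5.14 and 5.70, AT5G45500 with AT5G45510, at 6.47 and 3.14, and CYP71B23 with CYP71B24, at -2.63 and -2.20. Shuffling the values gave a median of 7 same-way pairs and a permutation p of 0.0276, but the test ran on the data that prompted it, and without AT4G01910 and AT4G01920, seen first, 12 pairs were left with a permutation p of 0.0559, so chance placement stays open. Probe sets shared between tandem copies stay open as well: 0% of the pairs held one marked as shared, but the 503 probe sets with several genes had been left out beforehand and 2.08% of the 13217 probe sets tested are so marked, so the count could hardly have come out otherwise. A DNA segment of another strain linked to ALN cannot be told apart from no such segment, as the odds ratio of a large change among the 447 genes within 5000 locus numbers of ALN was 1.47 (95% interval 0.88 to 2.33). Shared control of neighbouring genes was not tested.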
